A study of Homo sapiens with 6 samples.

How the data were processed

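The data were RNA-seq libraries from non-polysomal sucrose gradient fractions of HCT116 cells, parental or with a LARP1 knockout. Per the labels, cells were treated with TAK228 at 250 nM for 48 h with the drug refreshed after 24 h, 1 mg of lysate was separated on gradients of 10% to 50% sucrose, and 20% of the volume of each non-polysomal fraction was pooled and spiked with ERCC RNAs. Per the labels' protocols, 1 µg of RNA was depleted of ribosomal RNA before library preparation, and reads were paired, 150 bases long. For the TSS libraries, per the labels' protocols, the parental RNA was dephosphorylated, decapped and ligated to an RNA oligonucleotide at its newly exposed ends. STAR 2.6, RSEM, SAMtools, DESeq2 and the GRCh38 build are named in the submitters' processing notes; the annotation release and the use of strand are not given in the sources used here.

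One table of 14574 genes was used. It held 6 columns of signal that the authors deposited as gene read counts divided by 1 size factor per library, here called normalised read counts. It also held the authors' comparison, per the file headers, with a log2 fold change, its standard error, a linear fold (ratio, parental over knockout), a test score, p-values with their adjusted values, and the −log10 of the adjusted p-value. The deposited fold changes followed the mean of the 4 parental libraries, TSS included, over the mean of the 2 knockout libraries (median absolute difference 0.00294 in log2, against 0.0949 for the 2 RNA-seq libraries alone). The authors' adjusted p was NA for 1 gene and stayed NA. Every gene had at least 5 reads in at least 2 of the 6 libraries. In every library 100% of the deposited signal values were whole multiples of the value of 1 read, within a tolerance of 0.001 reads, so whole reads were recovered and summed to give the depth. The table held 0 ERCC rows, so the size factors could not be rebuilt from spike-in counts. Relative to median-of-ratios factors of the genes, the deposited factors differed by -0.09 and -0.19 log2 units in the parental RNA-seq libraries, 0.04 and 0.29 in the knockout libraries, and 0.01 and -0.05 in the TSS libraries. Identifiers were matched to GENCODE release 29 (GRCh38) without version for 14535 genes (99.7%), and with version for 13269; coordinates, 1-based, transcript lengths and 5′ ends come from that release.

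The test fixed before the data were examined was edgeR on counts, or limma on normalised values where no counts were given. The deposited values were size-factor-normalised, so limma-trend (limma 3.58.1, R 4.3.3) was run on log2(value + 1) with the deposited scaling. Genes with a value of at least 1 in at least 2 of the 4 RNA-seq libraries entered (14561 genes). The 2 parental and 2 knockout RNA-seq libraries were compared by genotype alone, two-sided, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. The estimated prior degrees of freedom were infinite, so each gene's spread came from the trend over mean level. Groups of 2 allow no exact permutation p under 0.333. No pair of libraries agreed within sampling noise, so all were counted as separate. The median chi-square over its expected median ran from 1.75 between the knockout libraries to 8.50 between a TSS and a knockout library. Among parental libraries it reached 2.72, between an RNA-seq and a TSS library, and was 2.16 between both RNA-seq libraries. Reads are not counted by molecule, so intervals and floors cover counting error only; a floor is 3 reads over the group.

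The 23 gene lists were written before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and with the correlation estimated, and with fry, adjusted over the lists. No call by camera with the preset correlation held with the estimated one (8 lists against 0). TOP lists were also set against 10000 random lists matched on decile of mean level. Named genes followed a rule: LARP1; RPS6, RPL5, RPL11, EEF1A1, EEF2, PABPC1, TPT1, ACTB and GAPDH; the 8 largest rises and 8 largest falls among called protein-coding or named genes above the median of mean level whose knockout libraries both lay on 1 side of both parental libraries; per list the 2 members with the smallest adjusted p; and, for a list with no called member, its most abundant member. The comparison of TSS with RNA-seq libraries, which had been planned without a test per gene, and the list tests with an estimated correlation after centring (0 lists called) were added after the data were seen. TUT1, the genes named as differing between TSS and RNA-seq libraries, and the genes of the other observations were named after their values were seen.

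Centring subtracts each library's median log2 value. The other alternatives, set before the data were examined, were TMM factors of the recovered reads, no filter, a minimum of 5 in every library, pseudocounts of 0.1 and 5, no intensity trend, an absolute log2 fold change of at least 1, a replicate block, and each replicate left out. Added after the data were seen were edgeR 4.0.16 (with deposited or TMM factors) and DESeq2 1.42.0 on the recovered reads, the TSS libraries in place of the parental ones, the mean of RNA-seq and TSS values per parental RNA, and, for TSS against RNA-seq, the RNA sample as a block in limma and edgeR. Those libraries are paired because the labels give them the same RNA sample; their replicate differences had a correlation across genes of 0.051, or 0.099 over 12264 genes of at least 10, and with the samples crossed limma called 2 genes. On the recovered reads with deposited factors, edgeR called 4027 genes and DESeq2 2866. Each test was tested on simulated data for the knockout comparison, over 14557 genes with 200 changed. Limma recovered 57.7% of changes of 1 log2 unit and 87.4% of changes of 2, with 9 false calls (5.81% of calls). EdgeR recovered 58.8% and 86.4% with 5 false calls, and DESeq2 44.3% and 79.6% with 0 false calls. The simulation gave each gene the spread of its level and used known size factors, close to what limma assumed. Its share of false calls therefore need not hold for the real libraries. In a separate draw in which only 1 list was shifted, camera with the preset correlation called 0 of 200 unchanged lists. Its genes were drawn independently, so it does not test camera on correlated members. In the real libraries the estimated correlation was 0.82 for the 60S, 0.78 for the 40S and 0.66 for the other TOP list. Polysomal and whole-cell RNA were not analysed here, so a level in this fraction cannot be split into mRNA abundance and distribution across the gradient. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.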

Results

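HCT116, an established human colorectal carcinoma line, was studied as parental cells and as cells carrying a knockout of LARP1. LARP1 is an RNA-binding protein that recognises the cap and the 5′ terminal oligopyrimidine (TOP) motif, the run of pyrimidines that opens mRNAs for ribosomal proteins and several translation factors. All cells had received TAK228, an inhibitor of the mTOR kinase, at 250 nM for 48 h. RNA was taken from the non-polysomal part of sucrose gradients, between the small-subunit and monosome peaks, so each value is a level in that fraction and not in the whole cell. There were 2 parental RNA-seq libraries, 2 knockout RNA-seq libraries and 2 transcription start site (TSS) libraries made from the parental RNA. The table listed 14574 genes. The reads behind it summed to 19038642 and 25323973 in the parental RNA-seq libraries, 22039174 and 21388111 in the knockout libraries, and 26955481 and 24446561 in the TSS libraries. Mitochondrial 16S ribosomal RNA (MT-RNR2) took 55.3% and 57.9% of the reads in the parental RNA-seq libraries and 63.1% and 62.5% in the knockout libraries. Outside the mitochondrial genes, 6267820 to 9063478 reads remained per library. Values are normalised read counts, given as mean ± SD with n = 2 libraries per group unless stated otherwise, and every fold change is log2(value + 1) in the knockout minus the parental cells, a scale that understates changes of low genes. The labels call the libraries of a group biological replicates without naming separate cultures, so the spread between these libraries may be technical. The limma p-values use that spread only as a trend over mean level, not as each gene's own spread.

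The comparison of both genotypes asks which mRNAs differ in level in the non-polysomal fraction of cells under mTOR inhibition. Without polysomal or whole-cell RNA, it cannot tell retention in the fraction from mRNA abundance. Without untreated cells, it cannot show whether a difference depends on the drug. LARP1 itself fell 2.19-fold in the knockout, with 701 ± 97.3 in parental and 320.0 ± 50.9 in knockout libraries (log2 fold change -1.13, SE 0.18, limma adjusted p = 2.86e-09). The gene (ENSG00000155506.16) lies on chromosome 5, 154712902 to 154817607 in GRCh38. The single libraries read 633 and 770.3 in the parental cells and 356 and 284 in the knockout cells, so LARP1 mRNA was still present. The labels do not say which part of the gene was edited, and an edit that stops the protein need not remove the mRNA.

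Most genes that changed were lower in the knockout fraction. Of the gene lists, the 3 lists of TOP mRNAs had the lowest medians (-2.97, -2.73 and -2.75), while VIM, which encodes the intermediate filament protein vimentin, and BMP4, a secreted growth factor, rose by 6.63 and 3.44. GAPDH, a glycolytic enzyme, fell (42702 ± 1328 in parental and 18411 ± 1411 in knockout libraries, log2 fold change -1.22, SE 0.15, limma adjusted p = 8.99e-15). ACTB, cytoskeletal actin, gave 4216 ± 415 in parental and 3984 ± 320.0 in knockout libraries, a log2 fold change of -0.08 (limma adjusted p = 0.725) that turned to 0.23 (limma adjusted p = 0.0418, the lowest among its alternatives, the highest being 0.995) when each library was centred on its median gene. The ACTB value was 0.0017 without knockout replicate 2 and 0.020 without parental replicate 2. GAPDH has pseudogenes and ACTB close paralogs, so both values are uncertain. Of 14561 genes tested with limma, 3649 fell and 549 rose at an adjusted p under 0.05. The median gene had a log2 fold change of -0.29, so the split depended on scaling: lower genes made up 86.9% of the calls with the deposited scaling and 52.7% after centring, where 2365 fell and 2119 rose. All 2365 were among the 3649, and 546 of the 549 rises were kept. Without parental replicate 1, parental replicate 2, knockout replicate 1 or knockout replicate 2, the number called was 2769, 2214, 2532 and 1367 in turn. With 2 libraries per group, the spread came wholly from limma's trend over level, so a gene whose own replicates differ was given the spread of its level.

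**Figure D1:**
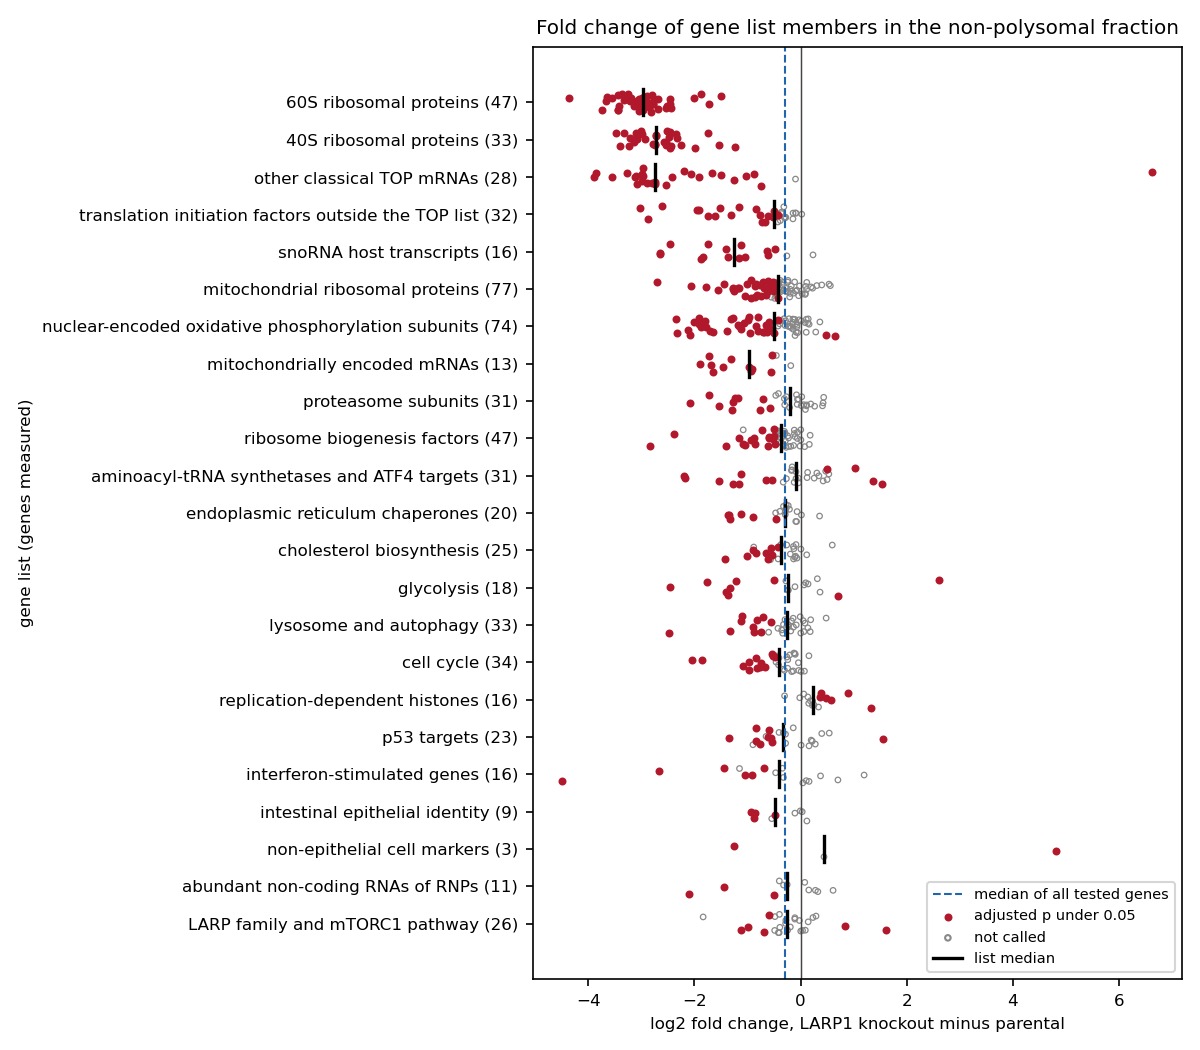
Each point is 1 gene, placed by its log2 fold change (knockout minus parental) on the horizontal axis and by its gene list on the vertical axis. Red points passed an adjusted p under 0.05 with limma, open grey points did not, black bars are list medians, and the dashed line marks the median of all tested genes at -0.29. The 3 TOP lists sit at medians of -2.97, -2.73 and -2.75, and VIM is the point at 6.63.

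All members of both ribosomal protein lists fell in the knockout fraction. In the large subunit, 47 of 47 fell and 0 rose, with the same counts adjusted over the list alone (47 lower), and the median log2 fold change was -2.97, or -2.66 after centring. In the small subunit, 33 of 33 fell and 0 rose (also 33 lower adjusted over the list alone), with a median of -2.73, or -2.42 after centring. RPL10 fell most of the ribosomal proteins, 20.5-fold, with 89901 ± 1149 in parental and 4390.3 ± 272 in knockout libraries (log2 fold change -4.36, SE 0.15, limma adjusted p = 8.27e-188). RPL3 fell 13.4-fold (-3.74, SE 0.14, limma adjusted p = 4.47e-143) and RPL5, a partner of the 5S ribosomal RNA, 12.6-fold (-3.65, SE 0.14, limma adjusted p = 2.10e-137). RPL11, the other 5S partner, fell 6.86-fold from 23229.9 ± 1868 to 3383 ± 243. In the small subunit, RACK1, a scaffold protein on the 40S head, fell 11.2-fold (-3.49, SE 0.15, limma adjusted p = 9.00e-121), RPS4X 10.6-fold (-3.40, SE 0.14, limma adjusted p = 4.98e-118), and RPS6, a substrate of S6 kinase, 6.74-fold from 80132 ± 243 to 11913 ± 1122. Ribosomal protein genes share sequence with many pseudogenes, so their exact values are uncertain.

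Among the 28 other classical TOP mRNAs, 26 fell and 1 rose (26 lower and 1 higher adjusted over the list alone), with a median of -2.75, or -2.44 after centring. NAP1L1, a histone chaperone, fell 14.9-fold (-3.90, SE 0.15, limma adjusted p = 1.14e-146) and EIF3E, a subunit of initiation factor eIF3, 14.4-fold (-3.85, SE 0.14, limma adjusted p = 1.79e-150). EEF1A1, the elongation factor that delivers aminoacyl-tRNA, fell 8.44-fold from 768742 ± 4301 to 91299 ± 8027. EEF2, the translocation factor, fell 7.80-fold, TPT1 4.17-fold and PABPC1, the cytoplasmic poly(A)-binding protein, 2.84-fold. EEF1A1 has many processed pseudogenes, so its value is uncertain. VIM was the member that rose, and TUT1 was not called, at -0.10 (limma adjusted p = 0.776), or 0.22 after centring. The 3 TOP lists together took 45.4% ± 0.284 of the reads outside mitochondrial genes in the parental libraries and 14.1% ± 0.168 in the knockout libraries, a share that does not depend on the scaling. Both knockout libraries lay below both parental libraries for 106 of the 108 members, against 16.7% of genes by chance and 50.4% of all 14561 genes tested. After centring these were 106 members and 31.3% of all genes tested. The median of the 108 members was -2.87, below the lowest of 10000 random lists matched on mean level, which ran from -0.62 to -0.17. The list tests passed with camera's preset correlation of 0.01, at adjusted p = 1.44e-264 for the large subunit, 6.12e-159 for the small subunit and 1.93e-84 for the other TOP mRNAs. None of the 3 held when the correlation among members was estimated from these 4 libraries (camera adjusted p = 0.265 with an estimated correlation for each). That version of camera also takes its degrees of freedom from the 4 libraries and not from the genes. Correlation among members alone need not explain the loss. The fry test, which asks whether a list moved one way without comparing it with other genes, gave adjusted p = 0.00953, 0.00953 and 0.0199. The shift of the median gene under the deposited scaling therefore enters it. No other list passed fry. Among lists that camera called, fry adjusted p was 0.0515 for snoRNA hosts and 0.0829 for other initiation factors. It was 0.0761 for oxidative phosphorylation, 0.0761 for histones and 0.102 for mitochondrially encoded mRNAs.

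**Figure D2:**
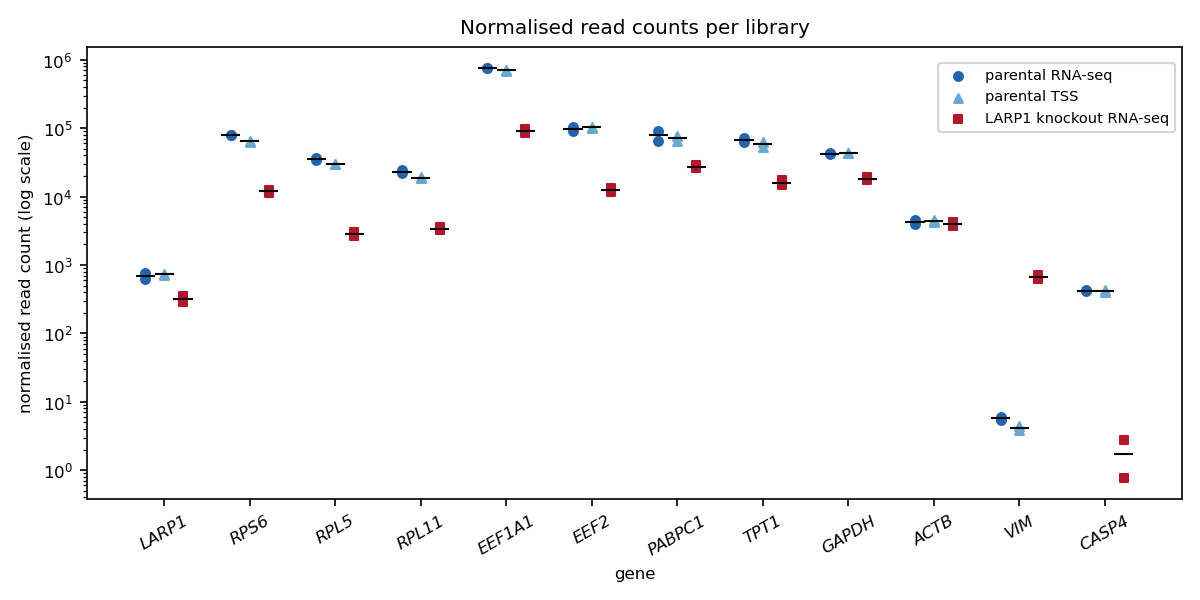
Normalised read counts on a log axis for 12 genes, with 1 point per library and a short black bar at the mean of each pair. Parental RNA-seq, parental TSS and knockout RNA-seq libraries are drawn side by side. The knockout points lie below the parental ones for LARP1, the TOP mRNAs, GAPDH and CASP4, above them for VIM, and overlap them for ACTB.

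**Figure D3:**
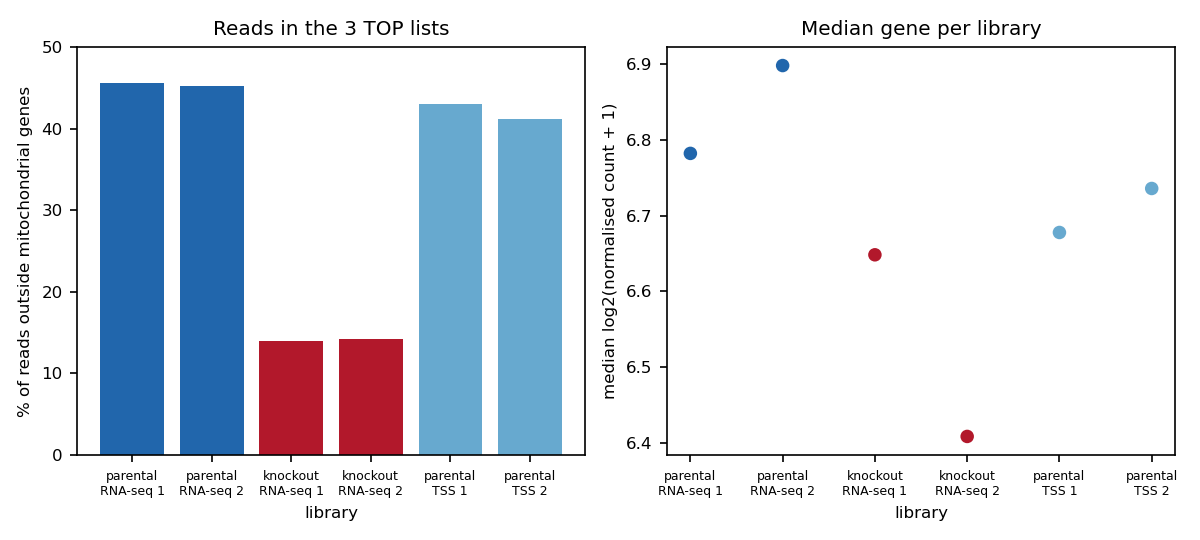
The bars (left) show the percentage of reads outside mitochondrial genes that fell in the 3 TOP lists, 1 bar per library, from 0. The points (right) show the median log2(normalised count + 1) of each library, which was 6.78 and 6.90 in the parental RNA-seq libraries and 6.65 and 6.41 in the knockout libraries.

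Of the initiation factors outside the TOP list, 18 of 32 fell and 0 rose (20 lower and 0 higher adjusted over the list alone), with a median of -0.51, or -0.19 after centring. EIF3K and EIF3M, both subunits of eIF3, fell 8.16-fold (-3.03, SE 0.17, limma adjusted p = 3.23e-69) and 7.35-fold (-2.88, SE 0.16, limma adjusted p = 2.59e-73). The list passed at camera adjusted p = 2.06e-08 and was lost at adjusted p = 0.827 with an estimated correlation. Of the snoRNA host transcripts, whose introns carry small nucleolar RNAs and whose spliced RNAs often open with a TOP motif, 14 of 16 fell and 0 rose (14 lower and 0 higher adjusted over the list alone). Their median was -1.26, or -0.95 after centring (camera adjusted p = 1.80e-15, and adjusted p = 0.683 with an estimated correlation). GAS5 fell 6.30-fold (-2.66, SE 0.15, limma adjusted p = 1.25e-69) and ZFAS1 6.27-fold (-2.65, SE 0.15, limma adjusted p = 8.60e-69); ZFAS1 is annotated as antisense, and its reads may include those of its partner. Of the ribosome biogenesis factors, 17 of 47 fell and 0 rose (17 lower and 0 higher adjusted over the list alone), with a median of -0.37, or -0.06 after centring, and the list did not pass (camera adjusted p = 0.0927), except without knockout replicate 1 (camera adjusted p = 0.00454, the lowest among its alternatives, the highest being 0.946). FBL, the rRNA methyltransferase fibrillarin, fell 7.12-fold (-2.83, SE 0.17, limma adjusted p = 1.57e-60) and NOB1, the nuclease that finishes 18S rRNA, 5.21-fold (-2.38, SE 0.17, limma adjusted p = 1.34e-40). Among the non-coding RNAs of RNPs, 3 of 11 fell and 0 rose (3 lower and 0 higher adjusted over the list alone), and the median was -0.25, or 0.06 after centring, with camera adjusted p = 0.904. NEAT1, the scaffold of paraspeckles, fell 2.73-fold (-1.45, SE 0.16, limma adjusted p = 2.98e-18), a call lost without knockout replicate 2 (limma adjusted p = 0.0684, the highest of its alternatives, the lowest being 1.67e-18). RNU4-1, a spliceosomal RNA with near-identical copies and so an uncertain value, fell 4.28-fold (-2.10, SE 0.26, limma adjusted p = 4.39e-14); its log2 fold change was -3.61 with the TSS libraries as parental libraries and -3.05 with the mean of RNA-seq and TSS values.

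Of the mRNAs encoded by the mitochondrial genome, 11 of 13 fell and 0 rose (11 lower and 0 higher adjusted over the list alone), with a median of -0.98, or -0.67 after centring (camera adjusted p = 2.06e-08, and adjusted p = 0.712 with an estimated correlation). With the TSS libraries as parental libraries the median was -1.68, and MT-CYB gave -2.47. MT-ND4L and MT-CYB fell 3.70-fold (-1.89, SE 0.15, limma adjusted p = 5.21e-34) and 3.29-fold (-1.72, SE 0.15, limma adjusted p = 1.60e-30), but their parental libraries differed, at 2655 and 5268 for MT-ND4L and 21488 and 39683 for MT-CYB. Without knockout replicate 2 the limma adjusted p was 0.0561 and 0.0506, the highest among their alternatives, whose lowest were 2.96e-60 and 5.72e-57. Of the nuclear-encoded subunits of oxidative phosphorylation, 37 of 74 fell and 2 rose (39 lower and 2 higher adjusted over the list alone), with a median of -0.50, or -0.19 after centring (camera adjusted p = 1.42e-05, and adjusted p = 0.946 with an estimated correlation). COX4I1, a cytochrome c oxidase subunit, fell 4.34-fold (-2.12, SE 0.16, limma adjusted p = 3.42e-40) and ATP5A1, the ATP synthase alpha subunit, 4.22-fold (-2.08, SE 0.15, limma adjusted p = 1.23e-40). Of the mitochondrial ribosomal proteins, 32 of 77 fell and 0 rose (32 lower and 0 higher adjusted over the list alone), with a median of -0.43, or -0.12 after centring. That list did not pass (camera adjusted p = 0.0627) but did after centring (camera adjusted p = 0.0338), with TMM factors (0.0316), without knockout replicate 1 (0.00179) and without knockout replicate 2 (0.022), within a range of 0.00179 to 0.946 over its alternatives. The share of reads in MT-RNR2, a mitochondrial ribosomal RNA, was higher in the knockout libraries (63.1% and 62.5%) than in the parental ones (55.3% and 57.9%). That share is of all reads and is not a level. On the deposited scaling, MT-RNR2 was itself lower in both knockout libraries than in both parental RNA-seq libraries. Both mitochondrial ribosomal RNAs together took 62.4% and 67.5% of the parental RNA-seq reads and 68.9% and 68.5% of the knockout reads. MRPL45 fell 6.49-fold (-2.70, SE 0.18, limma adjusted p = 1.14e-49) and MRPS27 4.16-fold (-2.06, SE 0.17, limma adjusted p = 2.24e-33).

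Of 16 replication-dependent histone mRNAs measured, 6 rose and 0 fell, while 10 were not called (0 lower and 6 higher adjusted over the list alone), with a median of 0.24, or 0.55 after centring, and 15 rose after centring. The list passed at camera adjusted p = 3.69e-04 and was lost at adjusted p = 0.712 with an estimated correlation. HIST1H1E, a linker histone, rose 1.49-fold (0.58, SE 0.15, limma adjusted p = 5.37e-04) and HIST1H3D, a core histone H3, 1.85-fold (0.89, SE 0.23, limma adjusted p = 7.57e-04). HIST1H1E was lost without either parental replicate (limma adjusted p = 0.151 without replicate 1 and 0.114 without replicate 2, against 9.71e-09 at the lowest) and without the intensity trend (0.11). HIST1H3D was lost without parental replicate 2, knockout replicate 1 or knockout replicate 2 (limma adjusted p = 0.102, 0.0532 and 0.0816, against 4.89e-07 at the lowest) and with the TSS libraries as parental libraries (0.0548). Histone genes are near-identical copies, so single values are uncertain.

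With the deposited scaling, the lists of ATF4 targets and glycolysis had called members in both directions. Called members of the proteasome, endoplasmic reticulum and cholesterol lists were all lower, adjusted over all genes tested. That contrast depended on scaling. After centring, 10 proteasome subunits were higher and 9 lower, against 7 and 6 in glycolysis. The endoplasmic reticulum list then had 1 higher and 5 lower, and the cholesterol list 1 higher and 5 lower. Among aminoacyl-tRNA synthetases and ATF4 targets, 8 of 31 fell and 4 rose (8 lower and 6 higher adjusted over the list alone), and after centring 16 rose and 7 fell. Their median was -0.09, or 0.22 after centring, with a mean of -0.15, while the median of all tested genes was -0.29. Camera, which compares a list with other genes, placed it above them without a call (camera adjusted p = 0.768). EPRS, the glutamyl-prolyl-tRNA synthetase, fell 4.55-fold (-2.19, SE 0.16, limma adjusted p = 1.86e-38) and SHMT2, a mitochondrial serine enzyme, 4.60-fold (-2.20, SE 0.18, limma adjusted p = 3.44e-32). In glycolysis, 7 of 18 fell and 2 rose (7 lower and 3 higher adjusted over the list alone), with a median of -0.24, or 0.08 after centring and camera adjusted p = 0.661. SLC2A1, the glucose transporter GLUT1, rose 6.10-fold (2.61, SE 0.19, limma adjusted p = 6.07e-42), while LDHB, a lactate dehydrogenase subunit, fell 5.52-fold (-2.46, SE 0.15, limma adjusted p = 2.49e-61). Of the proteasome subunits, 10 of 31 fell and 0 rose (11 lower and 2 higher adjusted over the list alone), with a median of -0.21, or 0.10 after centring (camera adjusted p = 0.549). PSMB4 and PSMB5 fell 4.23-fold (-2.08, SE 0.16, limma adjusted p = 3.12e-35) and 2.90-fold (-1.54, SE 0.18, limma adjusted p = 6.65e-17). Of the chaperones of the endoplasmic reticulum, 6 of 20 fell and 0 rose (7 lower and 0 higher adjusted over the list alone), with a median of -0.29, or 0.02 after centring (camera adjusted p = 0.431). CANX, calnexin, fell 2.50-fold (-1.32, SE 0.15, limma adjusted p = 2.08e-17) and SERP1 2.55-fold (-1.35, SE 0.18, limma adjusted p = 2.63e-12). In cholesterol biosynthesis, 9 of 25 fell and 0 rose (11 lower and 1 higher adjusted over the list alone), with a median of -0.37, or -0.06 after centring (camera adjusted p = 0.841). NSDHL fell 2.70-fold (-1.43, SE 0.26, limma adjusted p = 8.56e-07) and EBP 1.87-fold (-0.91, SE 0.23, limma adjusted p = 7.42e-04). Both were lost without knockout replicate 2 (limma adjusted p = 0.0611 and 0.0734, against 3.99e-08 and 6.02e-04 at the lowest), and EBP also without parental replicate 1 (limma adjusted p = 0.0527) and with the TSS libraries as parental libraries (limma adjusted p = 0.146).

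In the lysosome and autophagy list, 10 of 33 fell and 0 rose (10 lower and 0 higher adjusted over the list alone), with a median of -0.26, or 0.05 after centring (camera adjusted p = 0.768). NPC2, which carries cholesterol out of lysosomes, fell 5.55-fold (-2.47, SE 0.16, limma adjusted p = 1.23e-49) and LAMP1 2.53-fold (-1.34, SE 0.23, limma adjusted p = 1.34e-07). Of the cell cycle genes, 13 of 34 fell and 0 rose (16 lower and 0 higher adjusted over the list alone), with a median of -0.41, or -0.10 after centring (camera adjusted p = 0.155; 0.00937 without knockout replicate 1, in a range up to 0.946 over its alternatives). CDT1, a replication licensing factor, fell 4.16-fold (-2.06, SE 0.16, limma adjusted p = 5.75e-35) and CCNB2, a mitotic cyclin, 3.64-fold (-1.87, SE 0.20, limma adjusted p = 1.61e-19). Of the p53 targets, 8 of 23 fell and 1 rose (8 lower and 2 higher adjusted over the list alone), with a median of -0.33, or -0.02 after centring and a mean of -0.25, while camera placed the list above other genes without a call (camera adjusted p = 0.791). CCNG1 fell 2.56-fold (-1.36, SE 0.15, limma adjusted p = 1.64e-17) and PLK2, a polo-like kinase, rose 2.94-fold (1.56, SE 0.19, limma adjusted p = 1.77e-14). Of the interferon-stimulated genes, 6 of 16 fell and 0 rose (6 lower and 1 higher adjusted over the list alone), with a median of -0.41, or -0.10 after centring (camera adjusted p = 0.904). OAS3 fell 2.74-fold (-1.45, SE 0.26, limma adjusted p = 2.72e-07). BST2, tetherin, had 34 reads in the parental libraries and 0 in the knockout libraries, at least 20.1-fold lower against a floor of 3 reads over the group, and with BST2 at that bound the list median stayed -0.41. The TSS libraries of the same parental RNA held 20 BST2 reads, and against these the bound was at least 9.73-fold lower. Of the intestinal epithelial markers, 4 of 9 fell and 0 rose (4 lower and 0 higher adjusted over the list alone), with a median of -0.49, or -0.18 after centring (camera adjusted p = 0.768). KRT19 fell 1.80-fold (-0.85, SE 0.15, limma adjusted p = 1.03e-07) and EPCAM 1.90-fold (-0.93, SE 0.18, limma adjusted p = 3.62e-06), the latter lost without the intensity trend (limma adjusted p = 0.0693, the highest among its alternatives, against 1.22e-06 at the lowest).

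Only 3 markers of non-epithelial cells were measured, too few for a list test: 1 fell and 1 rose, with the same counts adjusted over the list alone (1 lower and 1 higher). Their median was 0.44, or 0.75 after centring. COL3A1, a fibrillar collagen, had 0 reads in the parental and 75 in the knockout libraries, at least 14.1-fold higher against a floor of 3 reads over the group. The TSS libraries of the same parental RNA held 3 COL3A1 reads, and against these the ratio was 17.1 with an exact 95% interval of 5.64 to 85.0 that covers counting error only. ACTA2, smooth muscle actin, fell 2.38-fold (-1.25, SE 0.41, limma adjusted p = 0.0111), a call lost after centring (limma adjusted p = 0.065), without parental replicate 2 (0.21), without knockout replicate 1 (0.0702) and without knockout replicate 2 (0.301), against 3.85e-05 at the lowest. It was also lost with TMM factors, without the intensity trend and with DESeq2. Of the LARP family and the mTORC1 pathway, 4 of 26 fell and 2 rose (4 lower and 2 higher adjusted over the list alone), with a median of -0.26, or 0.05 after centring and a mean of -0.22, while camera placed the list above other genes without a call (camera adjusted p = 0.65). The fallen members included LARP1, and the risen ones DDIT4L, an inhibitor of mTORC1 signalling, which went up 3.03-fold, with 23.0 ± 0.193 in parental and 72.0 ± 6.22 in knockout libraries (limma adjusted p = 5.41e-06).

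Among genes above the median of mean level, the 8 largest falls and 8 largest rises are given here or with their lists. CASP4, the inflammatory caspase-4 (chromosome 11, 104942866 to 104969436), went from 423 ± 8.90 to 1.75 ± 1.39, or from 661 reads to 5 (log2 fold change -7.37, SE 0.35, limma adjusted p = 8.57e-98). LINC01468, a long non-coding RNA, had 445 parental and 3 knockout reads, a ratio of 263 with an exact 95% interval of 89.5 to 1281 that covers counting error only. Its log2 fold change of -7.35 was -6.55 without knockout replicate 1 and -8.15 without knockout replicate 2. SPARC, a matrix glycoprotein, fell 69.7-fold (-6.12, SE 0.26, limma adjusted p = 5.92e-117), KIAA0040 33.3-fold (-5.06, SE 0.23, limma adjusted p = 4.64e-104), PDLIM1 25.9-fold (-4.70, SE 0.30, limma adjusted p = 8.73e-53) and IL18, an interleukin, 15.7-fold (-3.97, SE 0.18, limma adjusted p = 1.99e-101). RPL32P29, a ribosomal protein pseudogene whose reads may be shared with its parent gene and whose value is therefore uncertain, fell 24.9-fold (-4.64, SE 0.20, limma adjusted p = 9.12e-119). VIM (chromosome 10, 17228259 to 17237593) rose from 5.74 ± 0.502 to 668 ± 59.6, or from 9 reads to 1847 (log2 fold change 6.63, SE 0.27, limma adjusted p = 2.46e-126). SEMA3C, a secreted semaphorin, rose 21.9-fold (4.46, SE 0.24, limma adjusted p = 2.31e-74), RGS5 17.2-fold (4.11, SE 0.29, limma adjusted p = 3.86e-44) and BMP4 10.8-fold (3.44, SE 0.17, limma adjusted p = 8.26e-92). SOX4, a transcription factor, rose 7.29-fold (2.87, SE 0.17, limma adjusted p = 3.37e-58) and RNF43, a negative regulator of Wnt receptors, 6.54-fold (2.71, SE 0.21, limma adjusted p = 4.79e-35). HIST2H4B, which has a near-identical copy and so an uncertain value, rose 10.2-fold (3.35, SE 0.19, limma adjusted p = 5.74e-67). Its parental libraries read 43.1 and 206, the log2 fold change was 2.23 without parental replicate 1 and 4.47 without parental replicate 2, and the call was lost without knockout replicate 1 (limma adjusted p = 0.0595) or knockout replicate 2 (limma adjusted p = 0.0773, the highest among its alternatives, the lowest being 7.74e-75). With pseudocounts of 0.1 and 5, the log2 fold change was -8.08 and -6.00 for CASP4 and -9.26 and -5.61 for LINC01468, and VIM gave 5.97 with 5.

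The authors' deposited table holds their own DESeq2 comparison, whose fold changes followed the means of 4 parental libraries, TSS included, against 2 knockout libraries. Turned to knockout minus parental, it called 3534 genes lower and 629 higher at an adjusted p under 0.05. Among the 14561 genes tested here, 3094 were lower in both analyses and 456 higher in both, 0 were called with opposite signs, 648 were called here alone and 610 in the authors' deposited table alone. Across genes, which are not independent replicates, the fold changes of both had a Pearson r of 0.95. Both analyses used the same knockout and parental RNA-seq libraries, and the TSS libraries came from the same parental RNA. Their agreement was therefore largely built in and is not independent evidence. For LARP1 the authors' deposited table gave a log2 fold change, parental over knockout, of 1.16 and for RPL5 3.53.

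The TSS libraries, made by ligating an oligonucleotide to decapped 5′ ends of the parental RNA, address where the mRNAs found in this fraction start. Start positions were not analysed here, and the libraries are described by their counts per gene. TOP mRNAs took 42.1% ± 1.29 of their reads outside mitochondrial genes, against 45.4% ± 0.284 in the parental RNA-seq libraries. RPS6 read 64558 ± 2246, RPL5 30032 ± 502, EEF2 103267 ± 2109, LARP1 731 ± 20.2 and CASP4 413 ± 16.2. Over 12264 genes with at least 10 in every parental library, the Pearson r across genes was 0.984 between the first RNA-seq and TSS libraries and 0.982 between the second, against 0.983 between both RNA-seq libraries and 0.985 between both TSS libraries. Genes are not independent replicates in these values. In comparisons added after the data were seen, limma without pairing called 1 gene at an adjusted p under 0.05, 1453 had an unadjusted p under 0.05, and edgeR on the recovered reads called 72. Per the labels, an RNA-seq and a TSS library with the same number came from the same RNA sample. With the RNA sample as a block, limma called 252 genes, 231 lower and 21 higher in the TSS libraries, and edgeR 707, with 249 called by both. After centring, limma with the block called 85, 49 lower and 36 higher. With the block, 29 of 47 large and 23 of 33 small subunit mRNAs were lower in the TSS libraries and 0 higher (45 and 28 lower adjusted over the list alone), and after centring 3 and 5 were lower. Of 13 mitochondrially encoded mRNAs, 7 were higher and 0 lower (10 higher adjusted over the list alone), and 8 were higher after centring. RPS29 read 18604 ± 671 in the RNA-seq and 11966 ± 929 in the TSS libraries (-0.64, SE 0.06, limma adjusted p = 5.21e-05), and MT-ND1 6628 ± 1961 in the RNA-seq and 10738 ± 1582 in the TSS libraries (0.72, SE 0.07, limma adjusted p = 6.07e-05). The gene called without pairing was a long intergenic non-coding RNA (ENSG00000262202.4), higher in the TSS libraries by 2.63 log2 units (limma adjusted p = 0.0223, and 4.72e-08 with the block). Median log2 differences, TSS minus RNA-seq, were -0.28 for large and -0.31 for small subunit proteins and -0.11 for all genes. These differences mix the protocol with any difference in the scaling of the libraries.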

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

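The edgeR, DESeq2 and TSS alternatives, the block on the RNA sample and the mean of RNA-seq and TSS values included, were chosen after seeing the data. Of 69 named genes, 58 kept their sign and their side of the threshold in up to 17 alternatives each. Most of them were named for a small adjusted p or a large change in these data. This count therefore does not measure how stable the calls are over all genes. With the estimated correlation, 0 lists passed instead of 8. The medians of -2.97 (60S), -2.73 (40S) and -2.75 (other TOP mRNAs) then had a camera adjusted p of 0.265. The size of the correlation alone does not account for this loss, because the reference distribution also changes. With an estimated correlation, camera takes its degrees of freedom from the few libraries, and with the preset one from the number of genes. The preset p-values therefore do not reflect how few libraries there were. After centring, the other TOP mRNAs had an estimated correlation of 0.015, near the preset 0.01. Their camera adjusted p was still 0.165 with the estimated and 2.54e-32 with the preset correlation. With an absolute log2 fold change of at least 1, 2077 genes were called (1803 lower, 274 higher), by the alternative's own construction. Without the intensity trend 2244 were called (1962 lower, 282 higher), DESeq2 called 298 higher, and the TSS libraries as parental gave 922 higher, with 4 genes called in opposite directions; the cause was not tested. Scaling moved the split itself: centring gave 2365 lower and 2119 higher (52.7% lower), TMM factors 1976 higher (55.2% lower), and edgeR with TMM factors 2072 higher (55.4% lower). Leaving out each replicate gave 1367 to 2769 called, 1233 to 2416 lower and 116 to 389 higher, lowest overall without knockout replicate 2, with fewer samples and the lone library assumed to vary like the pair. ACTB reversed to 0.23 after centring, 0.22 with TMM factors and 0.21 with edgeR and TMM factors, and ran from -0.18 to 0.020 with replicates left out. For lists with no call, camera's direction turned after centring and with TMM factors; their medians, whose sign follows from the shift that both give to all genes, were 0.10 and 0.088 for proteasome subunits, 0.076 and 0.062 for glycolysis, and 0.058 and 0.045 for non-coding RNAs of RNPs. Camera's direction also turned without a call for interferon-stimulated genes with a minimum of 5 in every library (median -0.34, camera adjusted p = 0.872), and for 2 lists with replicates left out, whose medians ran from -0.44 to 0.093 for the non-coding RNAs and from -0.58 to -0.20 for cholesterol biosynthesis; the cause was not tested. The replicate block called 3159 genes (2771 lower, 388 higher) and 8 lists. Between genotypes the replicates share only a number: the replicate differences of both genotypes had a correlation across genes of -0.023. Scaling by spike-in counts was not run, as the table held 0 ERCC rows. At this depth and n, the simulation recovered 57.7% of changes of 1 log2 unit with limma, so a gene not called is not shown to be unchanged.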

Other observations

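The tests of scaling, pseudogenes, spike-in factors and shared reads were chosen after the results were seen; those of transcript length, copy number and the 5′ motif were written before their values were.

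Many genes outside the lists fell by more than 2 log2 units; examples are named after their values were seen. Among protein-coding genes outside all lists above the median of mean level, 123 were called with a log2 fold change under -2. They included LTA4H, a leukotriene hydrolase (-3.85, SE 0.15, limma adjusted p = 7.14e-135), IMPDH2, the guanine nucleotide synthesis enzyme (-3.40, SE 0.15, limma adjusted p = 6.58e-114), and IGBP1, a phosphatase regulator (-3.35, SE 0.18, limma adjusted p = 9.53e-79). Others were SLC25A6 (-3.23, SE 0.15, limma adjusted p = 1.88e-101), a nucleotide carrier, VDAC2 (-2.97, SE 0.16, limma adjusted p = 1.72e-73), a channel protein, and PHB2 (-2.78, SE 0.15, limma adjusted p = 2.01e-76). CD44, a cell surface receptor, fell from 10288 ± 948 to 1157 ± 102. EEF1A2 (-2.74) and RPL36AL (-2.63), whose symbols resemble those of listed TOP genes, were also among the 123. An annotated 5′ end opened with C and then 4 pyrimidines in 23 of the 123, ACTG1 included. That motif opened an annotated start in 7.12% of protein-coding genes outside the TOP lists. Genes for ACTB and ACTG1, near-identical actins, parted: ACTG1 fell (-2.99, SE 0.15, limma adjusted p = 9.35e-91; -2.68 after centring) and ACTB was not called.

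Of 73 gene families grouped by symbol after the data were seen, zinc finger genes (ZNF) stood above other genes with camera's preset correlation: 36 of 370 rose and 43 fell, and after centring 94 rose and 24 fell (medians -0.07 and 0.24). The camera adjusted p over the families was 0.00262, and adjusted p = 0.996 with an estimated correlation. Of 188 processed pseudogenes, 88 fell and 4 rose, with a median of -1.35, or -1.04 after centring. Of these, 49 were ribosomal protein pseudogenes by symbol, with 42 lower, 0 higher and a median of -2.74, and the other 139 had 46 lower, 4 higher and a median of -0.77, or -0.46 after centring. Pseudogenes share sequence with their parent genes, so these values are uncertain.

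The TOP mRNAs were the clearest pattern, and 3 technical explanations were weighed against loss of LARP1. Scaling does not account for it, since the median of the 108 members was -2.56 after centring. Short length does not either: TOP transcripts are shorter (median annotated length 848.5 against 2587 bases in other protein-coding genes), but their median of -2.87 lay below the lowest of 10000 lists matched on level and length, -0.88. Reads shifting to pseudogenes would raise those, and the 60 ribosomal protein pseudogenes had a median of -2.29 after centring, 45 lower and 0 higher. These tests leave a biological difference between the genotypes possible but do not show it. A difference in fractionation, pooling or library preparation between the genotypes was not tested and cannot be separated from genotype here. The knockout and parental cells can also differ in ways other than LARP1, which these libraries cannot separate. A lower level in this fraction may also reflect lower mRNA abundance, as whole-cell RNA was not analysed.

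The typical gene was lower in the knockout by 0.31 log2 units in library medians, which may be a real loss of mRNA from the fraction or an effect of size factors from spike-in counts. The medians differed by 0.116 within the parental and 0.239 within the knockout libraries. The exact permutation p (two-sided) was 0.333, the smallest that groups of 2 can give, so it decides nothing. As the table held 0 ERCC rows, both explanations cannot be told apart.

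Genes at the epsilon-globin locus on chromosome 11 fell together, a pattern found in the data: HBE1 (5268345 to 5505652, GRCh38) went from 1862 ± 62.9 to 142 ± 10.2 (-3.71, SE 0.17, limma adjusted p = 4.59e-97), and 5 of the 8 tested genes overlapping it fell, with OR51B4 at -3.36. A lower copy number of the wider region does not account for it, because the 12 other genes within 1 Mb had a median of -0.20 against -2.93 for the 8, although a change limited to the locus itself was not tested. All 8 lie on 1 strand inside overlapping gene models, so 1 long transcript may supply the reads of several. The read shares of the 5 that fell differed 2.33 times more between genotypes than between replicates (chi-square per degree of freedom, F test p = 0.143), a test that replaced one against counting error alone (chi-square p = 1.65e-04) after that result was seen, because the replicates also differed by more than counting error, so shared reads and separate genes cannot be told apart, and each value is uncertain.

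A hypothesis was tested that genes outside the TOP lists fell more often if an annotated 5′ end opens with C and then 4 pyrimidines. Of 880 protein-coding genes with the motif, 320 (36.4%) were called lower, against 2848 of 11471 (24.8%) without it, an odds ratio of 1.73 with a 95% interval of 1.498 to 1.998. The motif opened an annotated start in 7.12% of protein-coding genes outside the TOP lists, against 50.9% of the TOP list members. The odds ratio of being called lower was 1.67 when stratified by mean level and 1.72 by number of transcripts. After centring it was 1.88, with 25.8% called lower with the motif and 15.6% without it. The median log2 fold change was -0.40 with the motif and -0.28 without it. Genes with the motif were thus called lower more often, but whether they responded through the motif was not tested. The interval treats genes as independent, although all come from the same 4 libraries. Of genes without the motif, 24.8% were also lower. Only 50.9% of the TOP list members had an annotated start that matched, so annotated ends may differ from those used in these cells.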
